A study of Homo sapiens with 16 samples.

How the data were processed

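Libraries were made with a strand-specific mRNA kit and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0 and featureCounts 1.6.3 and the human build hg38, without giving settings. The authors deposited 1 table for the whole series, with a gene identifier per row and 16 value columns. Its value columns matched 0 samples by name, so all 16 were left unused and no expression value was computed. Samples were placed in 8 groups from their titles, but the groups could not be joined to the columns.

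A column was accepted only if its whole name stood in the labels of exactly 1 sample. Gene identifiers were looked up in a RefSeq gene table for GRCh38.p14, which gave a symbol to 27745 of the 28395 identifiers and left 650 without one. Of those with a symbol, 19175 were protein-coding genes, 4108 were long non-coding RNAs and 1853 were microRNAs. The 27 gene lists, with 816 distinct symbols, were fixed before the data were examined, and their symbols were looked up among the current symbols of these identifiers. The planned differential expression tests, list tests, rule for named genes and simulations were not run, because each needs columns assigned to groups.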

Results

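The series measured gene expression by RNA-seq in IMR90 cells, a human lung fibroblast line, here carrying hTERT and a doxycycline-inducible short hairpin RNA (shRNA). One line carried an shRNA against ATG7, which encodes the E1-like activating enzyme of the ubiquitin-like conjugation systems of autophagy. The other carried an shRNA against ATG13, which encodes a subunit of the ULK1 kinase complex that starts autophagy. The 16 samples formed 8 groups of 2, one for each combination of line, growth state and doxycycline. Senescent cells were sampled 10 days after bleomycin, a DNA-damaging drug given at 10 µg/ml for 24 h. Induced cells received doxycycline at 1 µg/ml for 10 days. The design asks how inducing an shRNA against either autophagy gene alters the transcriptome of proliferating and of senescent fibroblasts. Whether ATG7 or ATG13 mRNA fell was not analysed here.

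No expression level, fold change or test is reported for these groups. The deposited counts had 16 value columns headed only by a running number, and 0 of them could be matched by name to 1 of the 16 samples or to a group. Assigning columns by their order or by their values would have been a guess, so the columns were not used. The senescence comparison, the doxycycline comparison in each line and state, and the interaction between state and doxycycline were not analysed here. Sequencing depth per sample was likewise not analysed here. The labels named no non-targeting shRNA among these samples, so each doxycycline comparison in this design covers the drug and the shRNA together.

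The genes that the counts covered could be described without the value columns. Both shRNA targets were among the 28395 gene identifiers. ATG7 (identifier 10533) is a protein-coding gene on chromosome 3 from 11272397 to 11576353, and ATG13 (identifier 9776) is a protein-coding gene on chromosome 11 from 46617553 to 46674518, both on GRCh38. Autophagy genes were covered in full, with 37 of 37 symbols of the core machinery and 17 of 17 autophagy receptors present. The lysosome and TFEB target list had 47 of 48 symbols present. Cell cycle and DNA replication genes were also covered, with 51 of 51 present. The p53 targets had 32 of 32 present, the secreted inflammatory factors 42 of 42, and the secreted proteases and growth factors 42 of 42. For markers of other cell types, 13 of 13 epithelial, 10 of 10 endothelial and 12 of 12 blood cell symbols were present. Coverage by current symbol was incomplete for the replication-dependent histones, with 32 of 52 symbols present, and 52 of 52 were present once synonyms were added. It was also incomplete for the interferon-stimulated genes, with 40 of 41, and for nuclear-encoded oxidative phosphorylation, with 54 of 55. The mitochondrially encoded mRNAs were found for 0 of 13 symbols under the names used in the list, also with synonyms added. As 37 identifiers lay on the mitochondrial chromosome, this 0 reflects the names in the list and not an absence of mitochondrial rows. These counts say which listed symbols matched a row by name. They were read from the gene identifiers alone, so they carry no information on the samples or on whether a gene was expressed.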

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

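The alternatives for matching were chosen after seeing the data. The main match already ignored case. With punctuation and spaces ignored too, and only titles and descriptions searched, 0 of the 16 value columns matched 1 sample. No title held a running sample number, so this setting could add no match from the titles. Reading the number in the column name as a replicate number also matched 0 columns to 1 sample, since 1 and 2 were each the replicate number of 8 samples and no other column number was a replicate number. Of 816 listed symbols, 780 were found by current symbol and 803 with synonyms added. With synonyms, every list was found in full except the mitochondrially encoded mRNAs, with 0 of 13 under the names in the list. None of the alternatives planned before the data were examined was run, since each needs columns assigned to groups. No paired analysis was possible because the value columns carried no group or replicate label.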
